A study of Arabidopsis thaliana and Zea mays with 36 samples.

How the data were processed

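Linear RNA and circular RNA (circRNA, RNA closed on itself by back-splicing) were measured in leaves of Arabidopsis thaliana Col-0 and of maize inbred line B73 under graded water supply, per the labels. Libraries for circRNA were made from RNA digested with RNase R, an exonuclease that removes linear RNA, and libraries for linear RNA from undigested RNA. The labels name a well-watered group (WW) in each species and drought levels numbered from DT2 to DT5 in Arabidopsis and to DT4 in maize, with 2 biological replicates in each group and 36 samples in all. Treatment began 21 days after planting in Arabidopsis and 16 days after planting in maize, and leaves of 4 and at least 2 plants were pooled, per the labels' protocols. Reads were 150 bp paired-end. The soil moisture that belongs to each drought level is not given in the sources used here.

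Linear RNA was deposited as TPM per transcript, per the file headers, and each library summed to the same total, so that the deposited values keep no sequencing depth. The circRNA values are a signal scaled per library by the authors, and neither the scale nor the step that made it is given in the sources used here. Every circRNA value was a whole multiple of a step of its library, within 0.02 of a whole number for 100% of the values, and the smallest nonzero value was 2 steps; a step is taken below as the worth of 1 back-splice read, which no source states. The lengths deposited beside the circRNAs, in bp, equal the end minus the start of each location. The submitters' processing notes name BWA, edgeR, RSEM and the builds TAIR10 and B73 RefGen_v3, with no version, parameter or role. Coordinates of circRNAs are given as deposited.

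Groups were read from the sample titles. The columns of the tables carry the group and a number, and the titles carry the group and a letter, so a library was assigned to its group, and its number was not matched to a letter. The difference of circRNA and host gene within an RNA sample was planned before the data were examined. No source used here says that equal numbers mark the same RNA sample in both assays. This difference was therefore not the main test, and was formed between libraries of equal number only as an alternative. In its place the change of the circRNA among groups was compared with the change of its host as an interaction between unpaired libraries. The header of the Arabidopsis linear values has 1 cell more than its data, and the cell that states the unit was read as a caption; the literal reading is among the alternatives.

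Transcripts were summed to genes, 48359 to 27655 in Arabidopsis and 63235 to 39469 in maize. Genes with a TPM of at least 1 in 2 or more libraries were tested, 18938 in Arabidopsis and 22216 in maize. Values entered as log2(TPM + 1), with all libraries of a table in one fit, in limma 3.58.1 (moderated test with a mean-variance trend, two-sided) under R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. An adjusted p under 0.05 counted as a call. Each drought level was compared with WW, the highest with the lowest level, and all groups together by an F test. The values were read with pandas 2.3.3 and the data.table package (1.17.8), and figures drawn with matplotlib 3.10.9 under Python 3.11.15. Means are given with the SD of 2 libraries, and log2 changes with the standard error (SE) of the fit.

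The number of genes at a TPM of 1 or more ran from 16814 to 17885 per Arabidopsis library and from 19724 to 20530 per maize library. Correlations between the 2 libraries of a group were 0.977 to 0.988 in Arabidopsis and 0.966 to 0.978 in maize, and no library was identical to another. The summed steps of the circRNA libraries were 6549 to 10695 in Arabidopsis and 15260 to 23926 in maize, so most circRNAs rest on few reads; the total read depth is not given in the sources used here.

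The planned circRNA test was limma on log2(value + smallest nonzero value), 23.6 in Arabidopsis and 25.8 in maize. In both tables a circRNA at 0 in 1 library of a group was at 0 in the other too (4048 shared zeros against 1 single zero in Arabidopsis, 3869 against 0 in maize), so that the planned test reads listing and absence of listing as changes without spread. In 10 simulated tables with no difference between groups, where a group was set to 0 if either library had under 2 steps, it made on average 326 calls in Arabidopsis and 422 in maize. A second test was therefore added after the data had been seen. It takes the circRNAs listed in both groups compared and moderates the spread over every group in which a circRNA is listed. The moderation used infinite prior degrees of freedom in Arabidopsis and 168 in maize. Its SE and p thus rest wholly or almost wholly on a spread pooled over circRNAs. A version on the 4 libraries compared was tried first and replaced, after its counts had been seen, because it recovered fewer simulated changes. It was given the simulated values in steps and the version kept was given them scaled, so their recoveries are not strictly comparable.

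Gene lists were fixed before the data were examined for 22 Arabidopsis processes, with the plastid and mitochondrial genomes as further lists. They were tested with limma's camera at the preset correlation of 0.01 and with an estimated correlation, for lists with at least 5 tested members, two-sided, adjusted by Benjamini-Hochberg over the lists of a comparison. The fry test of limma, which asks whether members changed together without comparison with other genes, was also run. Its unadjusted p is given for the light-harvesting, photosystem and carbon fixation lists at DT2, DT3 and DT5. The lists cover dehydration and LEA proteins, ABA (abscisic acid) phosphatases, ABA kinases and ABF factors, ABA receptors, ABA synthesis and catabolism, stress transcription factors, compatible solutes, light harvesting, photosystem and electron transport, carbon fixation, cell wall loosening, aquaporins, leaf senescence, heat shock, jasmonate, salicylate and immunity, antioxidants, guard cell ion transport, the circadian clock, cell division, floral tissue and reference genes. Arabidopsis names come from a reference table of assembly TAIR10.1, used for names alone, in which 27445 of the 27655 genes and all 275 list identifiers were found. The sources used here pair no maize identifier with a name, so at most 2 maize identifiers are given in each direction, and no maize list was tested.

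Named genes were fixed by rule before the data were examined. From each list come the members with the smallest adjusted p, 4 at DT5 and 2 at each lower level. From the highest level come the 5 largest log2 changes in each direction among calls above the median level with both drought libraries beyond both WW libraries, and from the highest against the lowest level the 3 largest. The circRNAs named are those with the smallest adjusted p, the 5 highest means, those of GORK and of list genes, and those with the smallest adjusted p for the ratio to the host. List members called against the direction of their list at DT5, the genes plotted by library, the circRNAs called among those listed in both groups and the circRNAs used as examples of a ratio listed in every library were chosen after their values were seen. Genes of the RBCS, LHCB1 and CAB families and near-identical maize copies share reads, and their division by the authors' quantification is not given, so their single values are uncertain.

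Each result was recomputed under other pseudocounts, other filters on low values, a trimmed-mean rescaling between libraries that drops 30% of log ratios and 5% of mean levels, median centring, a replicate block, fits of the groups compared alone, a log2 threshold of 1, and with each library left out. The fits were tested on simulated data. For Arabidopsis DT5 against WW, 77% of genes changed by a log2 of 1 and 99% of those changed by a log2 of 2 were recovered among 18938 genes, with 15 false calls among 191. For maize DT4 against WW these were 30% and 95% among 22216 genes, with 10 false calls among 135. The test of circRNAs listed in both groups recovered 27.5% of 40 changed circRNAs at a log2 of 2 among 236 in Arabidopsis and 12.5% among 666 in maize, with 0 false calls by limma. The test of the ratio to the host recovered 100% of 40 at a log2 of 3 among 300 in each species. Its values were simulated without zeros or steps, so this recovery does not describe circRNAs at 0 in a group or at few steps. Of 200 lists with no change, camera gave p under 0.05 for 5 in Arabidopsis and 12 in maize. These lists were drawn at random from genes simulated independently of each other. The light-harvesting, photosystem and carbon fixation lists had estimated correlations of 0.76, 0.76 and 0.79. The simulation therefore does not test camera on lists with correlated members. Groups of 2 libraries left too few samples for a test of other splits. Leaving out a library also lowers the precision of a comparison, so a call near the threshold can be lost whichever library goes. A call lost in this way does not single out the library left out.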

Results

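Leaves of Arabidopsis and maize were sequenced for linear RNA and for circRNA at graded drought levels, with 2 libraries in each of the 5 Arabidopsis and 4 maize groups of each assay. The comparisons ask which linear RNAs and circRNAs differ between each drought level and the well-watered group (WW), whether they differ between the highest and the lowest drought level, and whether circRNAs change with the genes they come from. Linear values are TPM and keep no depth. The median gene lay above WW at every drought level, by a log2 of 0.12 at DT2, 0.22 at DT3, 0.41 at DT4 and 0.26 at DT5 in Arabidopsis and by 0.14 at DT2, 0.27 at DT3 and 0.27 at DT4 in maize. Changes of gene lists are therefore mostly given relative to the median gene, and counts of called genes against WW also after a trimmed-mean rescaling of the libraries.

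The largest rises in Arabidopsis linear RNA at DT5 were those of proteins made in seeds and drying leaves, which are thought to protect membranes and other proteins from water loss. LEA7 (AT1G52690) rose from 1.15 ± 0.622 to 8609.8 ± 739 TPM (SD, n = 2), a log2 change of 12 (SE 0.31, limma adjusted p = 6.05e-09). The dehydrin gene RAB18 (AT5G66400) rose by 10.66 (SE 0.28) from 22.0 ± 1.16 to 37323 ± 2705 TPM (SD, n = 2), and LTI65 (AT5G52300) by 10.34 (SE 0.30) to 3212 ± 32.9 TPM. The lipid transfer protein gene LTP4 (AT5G59310) rose by 10.72 (SE 0.43), and AT3G17520, the only member of the 5 largest rises without a symbol, by 10.47 (SE 0.29). LTI30 (AT3G50970) had the smallest adjusted p of the dehydration and LEA list, 2.79e-09, at a log2 change of 9.59 (SE 0.18), followed by LEA7, RAB18 and LEA4-5 (AT5G06760), which rose by 10.10 (SE 0.29). Of the 22 list members 21 rose and 1 fell, also adjusted over the list alone. The list median lay 4.74 above the median gene (camera adjusted p = 1.30e-08, adjusted p = 0.266 with an estimated correlation). COR15B (AT2G42530), picked after its value was seen, fell by 1.17 (SE 0.18, adjusted p = 2.54e-04).

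Genes of abscisic acid (ABA) signalling moved in opposite directions at DT5. The clade A PP2C phosphatases, which hold ABA signalling off, all rose, 9 of 9 also adjusted over the list alone. HAI1 (AT5G59220) rose from 1.99 ± 0.834 to 404 ± 50.4 TPM (SD, n = 2; log2 7.10, SE 0.36, adjusted p = 1.05e-07), HAI2 (AT1G07430) rose by 6.01 (SE 0.33), and ABI2 (AT5G57050) from 12.5 ± 0.445 to 297 ± 12.4 TPM. HAI3 (AT2G29380) was listed at 0 in WW and at 63.9 ± 1.34 TPM (SD, n = 2) at DT5 (adjusted p = 2.22e-08). The list median lay 4.21 above the median gene (camera adjusted p = 9.26e-05, adjusted p = 0.266 with an estimated correlation). Of 8 ABA kinases and ABF factors 7 rose and 0 fell by limma (7 and 0 at an unadjusted p under 0.05), also adjusted over the list alone. OST1 (AT4G33950), which opens anion channels in guard cells, rose from 9.29 ± 0.969 to 51.3 ± 1.77 TPM (SD, n = 2), and SNRK2.2 (AT3G50500), ABF1 (AT1G49720) and ABF2 (AT1G45249) rose by 1.82, 2.88 and 2.84. Their median lay 2.09 above the median gene (camera adjusted p = 1.78e-03, adjusted p = 0.266 with an estimated correlation).

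Of 8 ABA receptor genes 5 fell at DT5, also adjusted over the list alone, and 7 fell after rescaling. PYL4 (AT2G38310) fell by 4.06 (SE 0.70), and RCAR3 (AT5G53160), PYL1 (AT5G46790) and PYR1 (AT4G17870) changed by -1.99, -1.64 and -1.0. The list median relative to the median gene was -1.58 (camera adjusted p = 6.66e-03, adjusted p = 0.266 with an estimated correlation). Among genes of ABA synthesis and breakdown 6 of 9 rose and 2 fell, also adjusted over the list alone. NCED3 (AT3G14440), which makes the first committed precursor of ABA, rose from 4.2 ± 0.735 to 49.6 ± 5.50 TPM (SD, n = 2; log2 3.29, SE 0.24, adjusted p = 1.29e-06). AAO3 (AT2G27150) rose by 2.57, and the ABA-degrading hydroxylases CYP707A1 (AT4G19230) and CYP707A4 (AT3G19270) by 4.59 and 2.55. ABA2 (AT1G52340) and ABA1 (AT5G67030), picked after their values were seen, changed by -0.80 and -0.47. The call of ABA1 was lost without DT5 replicate 2 (adjusted p = 0.0558). The list as a whole did not pass camera (adjusted p = 0.0750, adjusted p = 0.384 with an estimated correlation, 0.0370 after rescaling).

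Stress transcription factors and genes for compatible solutes were higher at DT5. DREB2A (AT5G05410), which binds promoters of dehydration and heat genes, rose from 0.720 ± 0.170 to 133 ± 19.6 TPM (SD, n = 2; log2 6.28, SE 0.19, adjusted p = 9.99e-09), RD26 (AT4G27410) by 4.14 (SE 0.20), DREB2B (AT3G11020) by 3.67 and NAC019 (AT1G52890) by 3.43. Of 14 such factors 11 rose and 0 fell by limma (12 and 0 at an unadjusted p under 0.05), also adjusted over the list alone. Their median lay 2.65 above the median gene (camera adjusted p = 3.86e-04, adjusted p = 0.266 with an estimated correlation). The sucrose synthases SUS3 (AT4G02280) and SUS1 (AT5G20830) rose by 5.98 (SE 0.18) and 4.18 (SE 0.13), the beta-amylase BAM1 (AT3G23920) by 3.56, and ALDH12A1 (AT5G62530), which breaks down proline, by 2.22. Of 13 solute genes 10 rose and 1 fell, also adjusted over the list alone, and 2 fell after rescaling. Their median lay 1.97 above the median gene (camera adjusted p = 3.20e-03, adjusted p = 0.266 with an estimated correlation). GolS1 (AT2G47180), picked after its value was seen, fell by 1.55 (SE 0.27).

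The photosynthesis genes of the lists on light harvesting, photosystems and carbon fixation all fell at DT5. The Rubisco small subunit RBCS2B (AT5G38420) fell by 9.86 (SE 0.54) from 6112 ± 113 to 5.76 ± 2.3 TPM (SD, n = 2), the carbonic anhydrase CA1 (AT3G01500) fell by 9.32 (SE 0.51), and the light-harvesting protein gene LHCB2.3 (AT3G27690) fell by 8.84 (SE 0.36). The other members of the 5 largest falls were AT2G10940, which dropped by 9.20 (SE 0.82), and the germin-like gene GER1 (AT1G72610), which dropped by 8.99 (SE 0.67). All 18 light-harvesting genes fell, as did all 25 of photosystems and electron transport and all 17 of carbon fixation, each also adjusted over the list alone and after rescaling. LHCB5 (AT4G10340) dropped by 5.19 (SE 0.17) from 6345 ± 304 to 173 ± 25.9 TPM (SD, n = 2). LHCB3 (AT5G54270), LHCB6 (AT1G15820) and LHCB4.2 (AT3G08940) changed by -4.86, -5.35 and -3.69. Relative to the median gene the light-harvesting list was at -3.89 (camera adjusted p = 4.71e-13, adjusted p = 0.266 with an estimated correlation).

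PSBQ-2 (AT4G05180) and PSBQA (AT4G21280), which belong to the oxygen-evolving complex, changed by -4.88 (SE 0.17) and -5.18 (SE 0.18), PSAN (AT5G64040) of photosystem I by -4.74 and PSBO2 (AT3G50820) by -4.12. This list was at -3.40 relative to the median gene (camera adjusted p = 1.08e-16, adjusted p = 0.266 with an estimated correlation). RCA (AT2G39730), the activase of Rubisco, dropped by 4.44 (SE 0.15) from 9703 ± 52.3 to 446 ± 50.7 TPM (SD, n = 2). RBCS3B (AT5G38410), GAPA (AT3G26650) and the bisphosphatase HCEF1 (AT3G54050) changed by -7.76, -3.91 and -3.27. The carbon fixation list was at -4.11 (camera adjusted p = 1.24e-12, adjusted p = 0.266 with an estimated correlation). Members of the RBCS and LHCB families share reads, and their single values are uncertain. Of 57 plastid genome genes 5 rose and 9 fell, 4 and 9 adjusted over the list alone and 5 and 10 after rescaling, and camera gave an adjusted p of 0.0750 (adjusted p = 0.569 with an estimated correlation). Of 38 mitochondrial genome genes 7 rose and 2 fell, 1 and 0 adjusted over the list alone and 5 and 2 after rescaling (camera adjusted p = 0.956).

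Genes that let water through membranes and loosen cell walls were mostly lower at DT5. The tonoplast aquaporin gene GAMMA-TIP (AT2G36830) dropped by 4.37 (SE 0.15) from 446 ± 31.7 to 20.6 ± 0.354 TPM (SD, n = 2). PIP2A (AT3G53420), PIP1C (AT1G01620) and PIP3 (AT4G35100) changed by -3.74, -5.02 and -2.91. Of 17 aquaporins 14 fell and 2 rose, also adjusted over the list alone, and the list was at -4.00 relative to the median gene (camera adjusted p = 4.41e-07, adjusted p = 0.266 with an estimated correlation). The risers, picked after their values were seen, were PIP1;4 (AT4G00430), up by 1.67 (SE 0.12), and PIP2;5 (AT3G54820), up by 1.43 (SE 0.25). The expansin gene EXPA8 (AT2G40610) dropped by 6.73 (SE 0.41) from 122 ± 4.31 to 0.165 ± 0.233 TPM (SD, n = 2). EXP3 (AT2G37640), EXPA10 (AT1G26770) and XTH8 (AT1G11545) changed by -5.12, -3.80 and -4.32. Of 16 cell wall genes 15 fell and 1 rose, also adjusted over the list alone, with the list at -4.16 (camera adjusted p = 7.37e-07, adjusted p = 0.266 with an estimated correlation). The riser was TCH4 (AT5G57560), up by 3.28 (SE 0.33).

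All 8 cell division genes fell at DT5, also adjusted over the list alone. CYC1BAT (AT5G06150), CYCA1;1 (AT1G44110), SYP111 (AT1G08560) and CYCB1;1 (AT4G37490) changed by -2.46, -1.87, -1.49 and -1.42. The list was at -1.72 relative to the median gene (camera adjusted p = 9.61e-04, adjusted p = 0.266 with an estimated correlation).

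Jasmonate and salicylate genes mostly fell at DT5. MYC2 (AT1G32640), the transcription factor through which jasmonate acts, went from 57.5 ± 10.6 TPM (SD, n = 2) in WW to a listed value of 0 (adjusted p = 7.85e-09). LOX2 (AT3G45140), of jasmonate synthesis, changed by -6.24 (SE 0.25), AOS (AT5G42650) by -2.3 and JAZ5 (AT1G17380) by -2.62, while JAZ1 (AT1G19180), picked after its value was seen, rose by 1.34 (SE 0.12). Of 12 jasmonate genes 10 fell and 1 rose, also adjusted over the list alone, at -2.50 (camera adjusted p = 1.13e-04, adjusted p = 0.266 with an estimated correlation). Of 9 salicylate and immunity genes 6 fell and 1 rose, PAD3 (AT3G26830), also adjusted over the list alone. WRKY70 (AT3G56400), PR5 (AT1G75040), EDS1 (AT3G48090) and PAD4 (AT3G52430) changed by -3.31, -2.61, -1.68 and -1.61, and the list was at -1.78 (camera adjusted p = 0.0149, adjusted p = 0.398 with an estimated correlation).

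Most of the listed senescence genes rose at DT5. The sugar transporter gene SAG29 (AT5G13170) rose from 1.21 ± 0.233 to 423 ± 64.0 TPM (SD, n = 2; log2 7.58, SE 0.38), SAG13 (AT2G29350) by 3.69, and the chlorophyll breakdown genes ACD1 (AT3G44880) and PPH (AT5G13800) by 2.27 and 1.18. Of 13 senescence genes 9 rose, 8 after rescaling, and 2 fell, also adjusted over the list alone. The fallers, picked after their values were seen as was PAD3, were WRKY53 (AT4G23810) at -2.41 and SEN1 (AT4G35770) at -2.02. The list lay 0.92 above the median gene (camera adjusted p = 0.0300, adjusted p = 0.266 with an estimated correlation).

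Transcripts of small heat shock proteins, which keep unfolded proteins soluble, were higher at DT5 than in WW. HSP17.4 (AT3G46230) rose from 0.280 ± 0.198 to 159 ± 13.4 TPM (SD, n = 2; log2 6.97, SE 0.35, adjusted p = 1.05e-07) and AT1G53540 by 5.44 (SE 0.34). HSP21 (AT4G27670) and ATHSP22.0 (AT4G10250) were listed at 0 in WW and at 35.9 ± 8.17 and 18 ± 3.90 TPM (SD, n = 2). Of 13 heat shock genes 11 rose and 2 fell, also adjusted over the list alone, at 1.99 above the median gene (camera adjusted p = 3.20e-03, adjusted p = 0.266 with an estimated correlation). HSFA3 (AT5G03720) and HSFA7A (AT3G51910), picked after their values were seen, changed by -0.71 and -0.60. The call of HSFA3 was lost without any of WW replicate 1, WW replicate 2, DT5 replicate 1 and DT5 replicate 2 (highest adjusted p = 0.149), and that of HSFA7A without WW replicate 1, WW replicate 2 and DT5 replicate 2 (0.205).

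Clock genes, whose level depends on the time of harvest, were higher at DT5, with ELF4 (AT2G40080) up by 6.22 (SE 0.27), PRR5 (AT5G24470) up by 5.27 (SE 0.18) from 0.510 ± 0.0710 to 57.1 ± 1.93 TPM (SD, n = 2), TOC1 (AT5G61380) up by 2.56 and GI (AT1G22770) up by 1.66. Of 9 members 6 rose and 0 fell by limma (6 and 0 at an unadjusted p under 0.05), also adjusted over the list alone, at 0.73 above the median gene (camera adjusted p = 0.0171, adjusted p = 0.323 with an estimated correlation). The hour of harvest is not given in the sources used here. GORK (AT5G37500), the outward potassium channel of guard cells, rose from 1.76 ± 0.0710 to 54.1 ± 6.48 TPM (SD, n = 2; log2 4.31, SE 0.18, adjusted p = 3.84e-08) and the anion channel gene OZS1 (AT1G12480) by 1.31. MYB60 (AT1G08810), which controls stomatal movement, and the inward channel gene KAT1 (AT5G46240) changed by -2.52 and -1.35. Of 7 guard cell genes 2 rose and 4 fell, also adjusted over the list alone. The median change was -0.68, the mean 0.03 and the direction of camera down (adjusted p = 0.405).

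CAT1 (AT1G20630) rose by 2.13 (SE 0.13) at DT5, and FSD1 (AT4G25100), CSD2 (AT2G28190) and CAT2 (AT4G35090), which remove superoxide or hydrogen peroxide, changed by -1.73, -1.88 and -1.39. Of 8 antioxidant genes 3 rose and 3 fell, also adjusted over the list alone, with 4 falls after rescaling, a median of -0.18 against a mean of 0.14 and camera pointing down (adjusted p = 0.431). Of 3 floral genes 1 rose, AGL8 (AT5G60910), by 1.97, and 1 changed by -0.85, AG (AT4G18960), also adjusted over the list alone, with a median of -0.15 against a mean of 0.32. The call of AG was lost without WW replicate 1 or DT5 replicate 2 (highest adjusted p = 0.171). Of 5 reference genes PP2AA3 (AT1G13320) rose by 0.41 and UBQ10 (AT4G05320) by 0.33 and ACT2 (AT3G18780) fell by 0.58 (SE 0.09), also adjusted over the list alone. The rises were lost after rescaling, with adjusted p = 0.280 for PP2AA3 and 0.837 for UBQ10, and that of UBQ10 also without any of WW replicate 1, WW replicate 2, DT5 replicate 1 and DT5 replicate 2 (highest adjusted p = 0.161).

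In all, 8218 Arabidopsis genes were higher and 5328 lower at DT5 than in WW out of 18938 tested (limma, Benjamini-Hochberg), and after rescaling 6384 were higher and 6640 lower.

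**Figure D1:**
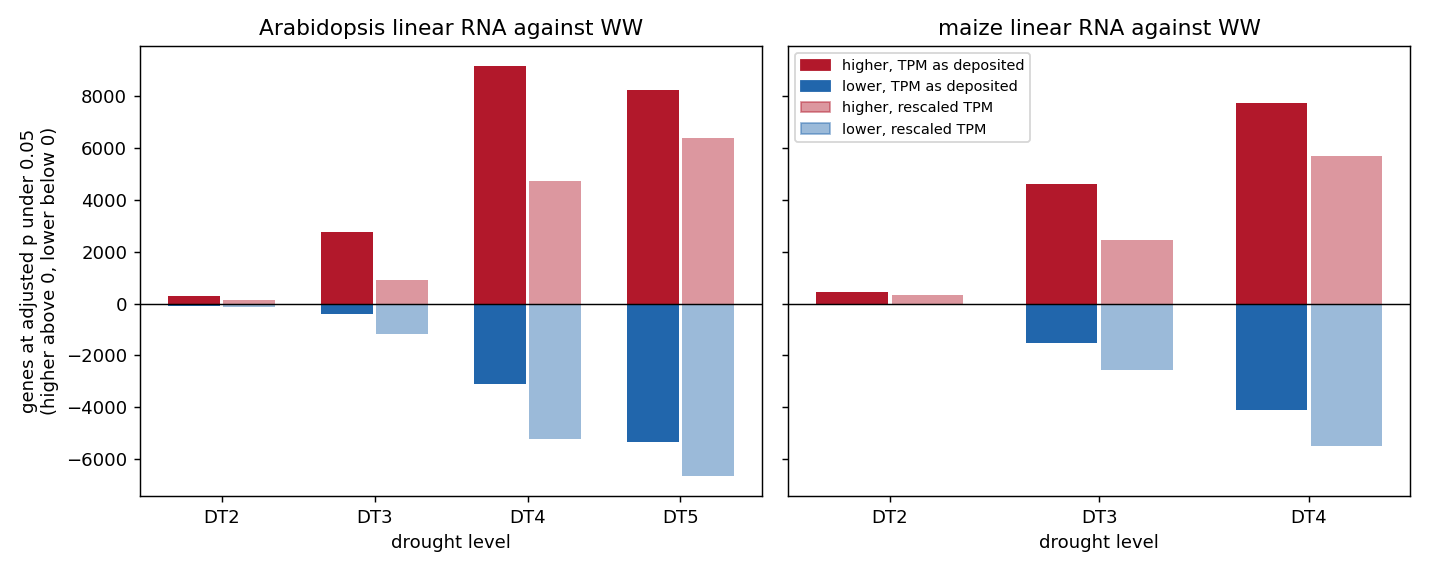
Number of genes past a limma adjusted p of 0.05 against WW (vertical axis, higher genes above 0 and lower genes below 0) at each drought level (horizontal axis) in Arabidopsis and maize, with TPM as deposited (dark bars) and rescaled (light bars). At Arabidopsis DT4 the deposited values give 9146 higher and 3100 lower genes and the rescaled values 4728 and 5226.

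**Figure D2:**
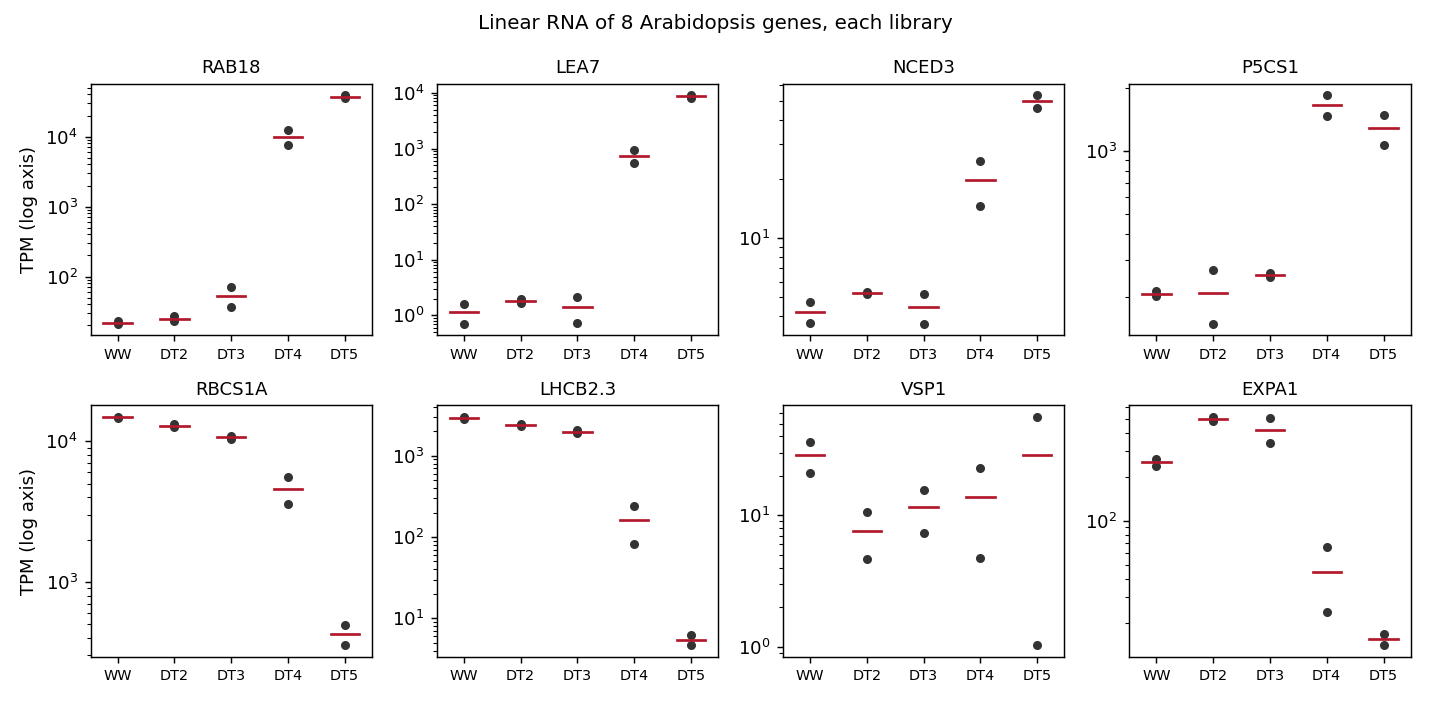
TPM of 8 Arabidopsis genes (log axes) in each library (points) with the group mean (line) in WW and DT2 to DT5, genes chosen after their values were seen. RAB18 and LEA7 lie far above WW at DT4 and DT5, where LHCB2.3 lies far below, and the 2 DT5 libraries of VSP1 lie apart.

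At DT4 in Arabidopsis the dehydration and LEA genes rose. LTI30 rose from 9.26 ± 1.68 to 1061 ± 286 TPM (SD, n = 2; log2 6.68, SE 0.18, adjusted p = 3.75e-08) and KIN1 (AT5G15960) by 6.45 (SE 0.21). Of 22 members 20 rose and 0 fell by limma (21 and 1 at an unadjusted p under 0.05), 21 and 1 adjusted over the list alone and 19 and 1 after rescaling, at 2.86 above the median gene (camera adjusted p = 3.03e-08, adjusted p = 0.282 with an estimated correlation). Of the PP2C genes 9 of 9 rose, also adjusted over the list alone, with HAI2 up by 5.83 (SE 0.33) and ABI1 (AT4G26080) by 2.31 (SE 0.14), at 2.01 above the median gene (camera adjusted p = 2.86e-04, adjusted p = 0.313 with an estimated correlation). All 8 kinases and ABF factors rose, also adjusted over the list alone, with SNRK2.2 up by 1.68 and ABF1 by 2.69, at 1.64 above the median gene (camera adjusted p = 5.74e-04, adjusted p = 0.282 with an estimated correlation). Of the receptors 4 fell and 1 rose, also adjusted over the list alone, 6 and 0 after rescaling, with PYL1 down by -1.31 and RCAR3 by -0.82, the list at -1.03 relative to the median gene (camera adjusted p = 0.0115, adjusted p = 0.313 with an estimated correlation). Of the 9 synthesis and breakdown genes 6 rose and 1 fell, 2 after rescaling, with CYP707A1 up by 3.31 and CYP707A2 (AT2G29090) by 2.79 (camera adjusted p = 0.184).

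The light-harvesting, photosystem and carbon fixation lists fell at DT4 in all 18, 25 and 17 members, also adjusted over the list alone and after rescaling. LHB1B1 (AT2G34430) dropped by 5.69 (SE 0.44) from 2952 ± 539 to 66.0 ± 50.5 TPM (SD, n = 2). LHCB2.3, PSBQA, PSAN, RBCS3B and RCA changed by -4.36, -2.56, -2.34, -3.80 and -1.85. The lists lay at -1.95, -1.76 and -2.02 relative to the median gene (camera adjusted p = 1.38e-14, 5.39e-20 and 7.26e-15, adjusted p = 0.281 with an estimated correlation for each). EXPA8 and XTH8 changed by -6.07 (SE 0.41) and -3.23 (SE 0.29), with 13 of 16 cell wall genes lower, 14 adjusted over the list alone and 15 after rescaling, the list at -2.87 relative to the median gene (camera adjusted p = 1.61e-09, adjusted p = 0.281 with an estimated correlation). GAMMA-TIP and PIP3 changed by -3.04 (SE 0.15) and -1.81 (SE 0.12), with 14 of 17 aquaporins lower and 2 higher, also adjusted over the list alone, 15 and 1 after rescaling, at -2.46 (camera adjusted p = 7.56e-11, adjusted p = 0.281 with an estimated correlation). All 8 cell division genes fell, also adjusted over the list alone, with SYP111 at -2.27 and CYC1BAT at -1.55 and the list at -1.68 relative to the median gene (camera adjusted p = 9.29e-06, adjusted p = 0.281 with an estimated correlation). LOX2 dropped by 2.56 (SE 0.25) and PDF1.2 (AT5G44420) went from 2.87 ± 0.424 TPM (SD, n = 2) to a listed value of 0, with 8 of 12 jasmonate genes lower, also adjusted over the list alone, 10 after rescaling, at -1.24 (camera adjusted p = 2.31e-05, adjusted p = 0.282 with an estimated correlation).

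NAC019 rose by 3.14 (SE 0.18) and DREB2A by 3.22 (SE 0.19) at DT4. Of 14 stress transcription factors 11 were higher and 0 lower by limma (11 and 0 at an unadjusted p under 0.05), also adjusted over the list alone, 8 and 1 after rescaling, at 1.07 above the median gene (camera adjusted p = 8.80e-03, adjusted p = 0.313 with an estimated correlation). SUS3 rose by 4.64 (SE 0.18) and ALDH12A1 by 1.92. SAG29 rose by 7.55 (SE 0.38), the senescence regulator NAC6 (AT5G39610) by 1.35, and GORK by 3.18 (SE 0.18) from 1.76 ± 0.0710 to 24.3 ± 4.81 TPM (SD, n = 2). HSP21 and ATHSP22.0, listed at 0 in WW, were at 6.01 ± 2.42 and 10.8 ± 2.52 TPM (SD, n = 2). KAT1, CSD2, EDS1 and WRKY70 changed by -1.3, -1.48, -0.64 and -1.2, while CAT1 rose by 0.91, PRR5 by 1.97, GI by 1.55 and AGL8 by 1.74. The calls of EDS1 and WRKY70 were lost without WW replicate 2 or DT4 replicate 1 (highest adjusted p = 0.119 and 0.236). The solute list (8 higher, 1 lower), the senescence list (10 and 1), the heat shock list (9 and 0), the clock list (8 and 1), the guard cell list (2 and 3) and the salicylate list (0 and 2, none adjusted over the list alone) did not pass camera, with adjusted p = 0.0785, 0.0520, 0.0818, 0.112, 0.153 and 0.0554. After rescaling the first 3 passed (adjusted p = 0.0198, 0.0112 and 0.0112, with 8 higher and 2 lower, 9 and 1, and 7 and 1; before rescaling 0.478, 0.313 and 0.478 with an estimated correlation), and the others did not (0.0806, 0.344 and 0.0999, with 4 and 1, 2 and 5, and 0 and 5). AT5G60390 and PP2AA3, both used as references, rose by 0.36 and 0.27 in TPM but were at -0.10 and -0.17 after rescaling. Their calls were lost without WW replicate 2 or DT4 replicate 2, and for PP2AA3 also without WW replicate 1 or DT4 replicate 1 (highest adjusted p = 0.123 and 0.161). At DT4 9146 genes were higher and 3100 lower than in WW, against 4728 and 5226 after rescaling.

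At DT3 in Arabidopsis a few members of several lists rose. LTP4 rose from 2.90 ± 1.42 to 85.1 ± 43.6 TPM (SD, n = 2; log2 4.41, SE 0.43, adjusted p = 4.68e-04), LTP3 (AT5G59320) by 3.22 (SE 0.34), SAG29 by 3.34 (SE 0.38) and NAC6 by 1.49 (SE 0.11). SNRK2.3 (AT5G66880) rose by 1.33 (SE 0.15) and SNRK2.2 by 0.94, and 3 of 8 kinases and ABF factors were higher, 5 adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.544 with an estimated correlation). CYP707A3 (AT5G45340) rose by 3.10 (SE 0.33) and CYP707A2 by 1.5, and the cell wall enzymes TCH4 and XTH33 (AT1G10550) by 3.0 (SE 0.33) and 2.11 (SE 0.21). The copper/zinc superoxide dismutases CSD2 and CSD1 (AT1G08830) fell to 38.2 ± 4.71 and 51.4 ± 0.679 TPM (SD, n = 2) from 152 ± 13.9 and 154 ± 5.06, and MYC2 fell by 1.11 (SE 0.17). These 13 genes stayed past adjusted p 0.05 whichever library was left out. The dehydration list, which holds LTP3 and LTP4, had 4 higher and 1 lower of 22 (camera adjusted p = 0.907), the ABA synthesis and catabolism list 3 higher of 9 (0.907), the cell wall list 2 of 16 (0.445) and the senescence list 6 of 13 (0.144). After rescaling these counts were 2 higher and 1 lower, 2 and 1, 2 and 0 (limma, 4 and 0 at an unadjusted p under 0.05 before rescaling), and 3 and 1.

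Jasmonate genes fell at DT3 in 5 of 12 members, 6 adjusted over the list alone and 8 after rescaling, at -1.02 relative to the median gene (camera adjusted p = 1.33e-09, adjusted p = 0.544 with an estimated correlation). The carbon fixation, photosystem and light-harvesting lists lay at -0.66, -0.50 and -0.43 (camera adjusted p = 2.67e-11, 5.21e-12 and 4.46e-07, adjusted p = 0.544 with an estimated correlation for each), although only 2, 1 and 1 of their members were called lower over all genes, 6, 0 and 0 adjusted over the list alone and 10, 10 and 2 after rescaling. These members were FBA2 (AT4G38970), RBCS1B (AT5G38430), FED A (AT1G60950) and LHCB4.3 (AT2G40100). By fry the unadjusted p of the carbon fixation, photosystem and light-harvesting lists at DT3 was 0.0716, 0.0732 and 0.199. Aquaporins lay at -0.44 with 2 lower, RD28 (AT2G37180) and GAMMA-TIP, 1 adjusted over the list alone and 5 after rescaling (camera adjusted p = 4.71e-05, adjusted p = 0.544 with an estimated correlation). Antioxidants had 2 higher and 3 lower, also adjusted over the list alone, and 0 and 3 after rescaling (camera adjusted p = 0.0434, adjusted p = 0.544 with an estimated correlation, 0.164 after rescaling). Plastid genome genes had 0 higher and 2 lower by limma (5 and 3 at an unadjusted p under 0.05), and camera pointed down (adjusted p = 0.0434, adjusted p = 0.733 with an estimated correlation) while the mean change was 0.15. The list did not pass camera with the replicate block (adjusted p = 0.0616) nor after rescaling (adjusted p = 0.999, pointing up).

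The other 20 named calls at DT3 were each lost when some library was left out. WRKY70 (up by 1.80) and LOX2 (at -1.21) were lost without WW replicate 1, DT3 replicate 1 or DT3 replicate 2 (highest adjusted p = 0.112 and 0.0864). GolS2 (AT1G56600, up by 0.82) and NF-YA5 (AT1G54160, up by 0.95) were lost without WW replicate 2, DT3 replicate 1 or DT3 replicate 2 (0.102 and 0.121). FT (AT1G65480, up by 1.22) was lost without WW replicate 1 or DT3 replicate 2 (0.0748), and RD28 (at -1.12), GAMMA-TIP (at -0.50) and PP2CA (AT3G11410, up by 0.69) without WW replicate 1, WW replicate 2 or DT3 replicate 2 (0.112, 0.235 and 0.197). ABI1, GI, SUS3, GORK, HSFA7A, PAD4 and MYBR1 (AT5G67300), which were higher, and FBA2, RBCS1B, FED A, LHCB4.3 and PRR9 (AT2G46790), which were lower, were lost without any of WW replicate 1, WW replicate 2, DT3 replicate 1 and DT3 replicate 2 (highest adjusted p = 0.203, for GI). After rescaling the calls of ABI1, PP2CA, GI, SUS3, GORK, PAD4 and MYBR1 were lost too (adjusted p from 0.0555 to 0.221). At DT3 2754 genes were higher and 420 lower, against 912 and 1156 after rescaling. The count of 3174 fell to 1028 without WW replicate 1, 854 without WW replicate 2, 712 without DT3 replicate 1 and 1047 without DT3 replicate 2.

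At DT2, the lowest level, the superoxide dismutase genes CSD1 and CSD2 and 6 of 12 jasmonate genes fell in Arabidopsis, and a senescence regulator rose. CSD2 dropped by 1.72 (SE 0.15, adjusted p = 1.59e-03) from 152 ± 13.9 to 45.7 ± 8.60 TPM (SD, n = 2) and CSD1 fell by 1.82 (SE 0.18, adjusted p = 3.33e-03). The antioxidant list that holds them had 0 higher and 2 lower of 8 by limma (3 and 2 at an unadjusted p under 0.05). It had 2 and 2 adjusted over the list alone and did not pass camera (adjusted p = 0.162). NAC6 rose by 1.42 (SE 0.11, adjusted p = 1.59e-03) from 25.8 ± 2.01 to 70.7 ± 2.96 TPM (SD, n = 2), and MYC2 dropped by 1.62 (SE 0.17, adjusted p = 3.52e-03). These 4 calls held whichever library was left out. Of 12 jasmonate genes 6 fell, 10 adjusted over the list alone and 8 after rescaling, at -1.29 relative to the median gene (camera adjusted p = 9.18e-20, adjusted p = 0.214 with an estimated correlation). TCH4 rose by 2.85 (SE 0.33) and CYP707A3 by 2.89 (SE 0.33), and both calls were lost without DT2 replicate 2 (adjusted p = 0.0533).

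CYP707A2 (up by 1.37) and JAZ5 (at -1.16) lost their DT2 calls without WW replicate 1, DT2 replicate 1 or DT2 replicate 2 (highest adjusted p = 0.0809 and 0.120), and SNRK2.2 (up by 0.66) without WW replicate 1, WW replicate 2 or DT2 replicate 2 (0.161). SNRK2.3 (up by 0.87), XTH33 (up by 1.24), LTP4 (up by 2.06) and MYBR1 (up by 0.71) lost theirs without any of WW replicate 1, WW replicate 2, DT2 replicate 1 and DT2 replicate 2 (highest adjusted p = 0.165, 0.148, 0.281 and 0.231), and LTP4 and MYBR1 also after rescaling (0.0677 and 0.111). Of the photosystem, light-harvesting and carbon fixation genes 0 were called at DT2 by limma, with 0, 0 and 2 at an unadjusted p under 0.05, while their lists lay at -0.25, -0.25 and -0.30 (camera adjusted p = 4.66e-05, 1.87e-04 and 1.78e-05, adjusted p = 0.689 with an estimated correlation for each). By fry, which does not set a list against other genes, the unadjusted p of these lists at DT2 was 0.414, 0.406 and 0.335. At DT5 fry gave 1.31e-06, 1.45e-06 and 2.99e-06. The kinases and ABF factors (2 higher, 3 adjusted over the list alone) lay at 0.16 and the dehydration list (1 higher, 2 higher and 2 lower adjusted over the list alone) at -0.12. Both had a camera adjusted p = 0.0366 and an adjusted p = 0.689 with an estimated correlation, and for the dehydration list camera pointed down while the mean change was 0.02. Neither passed with the replicate block (adjusted p = 0.0524). After rescaling the dehydration list had 0 higher and 1 lower by limma and a camera adjusted p of 0.130, and the kinases kept 2 higher (0.0241). At DT2 278 genes were higher and 78 lower, against 152 and 130 after rescaling. The count of 356 fell to 48 without WW replicate 1, 156 without WW replicate 2, 48 without DT2 replicate 1 and 40 without DT2 replicate 2.

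Between DT5 and DT2 the same kinds of Arabidopsis gene lay furthest apart. LEA7 was higher at DT5 by 11.57 (SE 0.31, adjusted p = 7.94e-09), AT3G17520 by 10.65 (SE 0.29) and RAB18 by 10.49 (SE 0.28), and RBCS2B, AT2G10940 and CA1 changed by -9.71 (SE 0.54), -9.19 (SE 0.82) and -9.01 (SE 0.51). Of the dehydration list 21 members rose and 1 fell, also adjusted over the list alone, at 4.92 above the median gene (camera adjusted p = 4.72e-10, adjusted p = 0.262 with an estimated correlation). All 18, 25 and 17 light-harvesting, photosystem and carbon fixation genes fell, also adjusted over the list alone, at -3.63, -3.13 and -3.74 relative to the median gene (camera adjusted p = 1.05e-11, 5.90e-15 and 2.68e-11, adjusted p = 0.262 with an estimated correlation for each). Of 12 jasmonate genes 8 fell and 1 rose, also adjusted over the list alone, at -1.21 (camera adjusted p = 0.0114, adjusted p = 0.455 with an estimated correlation). Between these levels 7379 genes were higher and 5920 lower at DT5, against 6399 and 6693 after rescaling. In all, 15489 genes differed among the Arabidopsis groups by the F test of limma.

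In maize linear RNA at DT4, GRMZM2G079440 rose from 7.27 ± 0.431 to 19420 ± 1944 TPM (SD, n = 2), a log2 change of 11.20 (SE 0.40, limma adjusted p = 3.08e-06), and was already higher at DT2 by 3.17 (adjusted p = 9.34e-03) and at DT3 by 7.92 (adjusted p = 4.45e-05). GRMZM2G179462 rose by 10.37 (SE 0.42) to 2007 ± 751 TPM (SD, n = 2). GRMZM2G070011 dropped by 8.79 (SE 0.22) from 646 ± 16.4 to 0.470 ± 0.255 TPM (SD, n = 2), and changed by -3.19 at DT2 (adjusted p = 9.94e-04) and -7.77 at DT3. GRMZM2G114588 dropped by 8.72 (SE 0.77). All 4 calls at DT4 held whichever library was left out. Of 22216 genes 7737 were higher and 4101 lower at DT4, against 5679 and 5474 after rescaling.

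At maize DT3 4603 genes were higher and 1513 lower, against 2466 and 2571 after rescaling. The total of 6116 fell to 2782 without WW replicate 1, 2159 without WW replicate 2 and 1952 without DT3 replicate 1. At maize DT2 454 were higher and 49 lower, against 317 and 71 after rescaling. The total of 503 fell to 112 without WW replicate 1, 71 without WW replicate 2, 38 without DT2 replicate 1 and 104 without DT2 replicate 2. Between DT4 and DT2 GRMZM2G096475 was higher by 9.39 (SE 0.67) and GRMZM2G063287 by 9.15 (SE 0.77), and GRMZM2G114588 and GRMZM2G114503 changed by -8.04 (SE 0.77) and -7.72 (SE 0.41). There 5954 genes were higher and 4464 lower, against 5158 and 5275 after rescaling, and the total of 10418 fell to 6942 without DT2 replicate 2. By the F test of limma 12212 genes differed among the maize groups.

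The Arabidopsis circRNA table held 1354 circRNAs, of which 1191 were exonic, 145 intergenic and 18 intronic, and 192 lay on the plastid genome. They came from 855 host genes, 162 of which had several circRNAs, and the plastid gene ATCG00020 had 118. The median length was 443 bp (137 to 157648). The listed circRNAs numbered 527 in WW, 512 at DT2, 492 at DT3, 591 at DT4 and 599 at DT5, on 14486, 15712, 14285, 19646 and 17358 steps over both libraries. The summed value was 106961 ± 9097 in WW and 130517 ± 19815 at DT5 (SD, n = 2). Only 106 circRNAs were listed in every library and 716 were listed in 1 group. The drought libraries listed 21 more circRNAs on average than the WW libraries (planned two-sided exact permutation of libraries, p = 0.667). This difference ran from 13.8 to 29.1 without 1 library and turned to -27.62 under a stricter detection minimum. Both libraries of a group listed nearly the same circRNAs, so libraries are not independent here. With groups permuted, chosen after the data had been seen, the exact permutation p was 1 (smallest possible 0.4).

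Some Arabidopsis circRNAs from genes of the drought lists were listed only at DT4, at DT5 or at both, while of all 1354 circRNAs 145 were listed in WW alone, 113 at DT2, 108 at DT3, 155 at DT4 and 195 at DT5. Whether list genes differed from the others in this was not tested. The circRNA of GORK, AT5G37500_C1 (exonic, chromosome 5, 14892940 to 14893314, TAIR10), had 0 steps in WW, DT2 and DT3, 5 at DT4 and 21 at DT5, where its value was 165 ± 136 (SD, n = 2). The circRNA of LTI65, AT5G52300_C1 (chromosome 5, 21237618 to 21238154), had 5 steps at DT4 and 17 at DT5 and was listed at 0 elsewhere, and that of RAB18, AT5G66400_C1 (chromosome 5, 26518803 to 26519053), had 24 steps at DT4 and 0 in every other group. Of 10 circRNAs from solute genes, which came from GolS2 and P5CS1, 1 was listed in WW, 3 at DT2, 2 at DT3, 3 at DT4 and 9 at DT5, with AT1G56600_C4 of GolS2 (chromosome 1, 21208601 to 21209274) at 25 steps at DT5. Carbon fixation genes had 8 circRNAs, with 1, 5, 2, 2 and 1 listed from WW to DT5, and dehydration genes 4, with 0, 0, 0, 2 and 3.

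Among Arabidopsis circRNAs listed in both groups compared, few calls were made. Their p-values rest on a spread pooled over circRNAs and give no weight to the spread of each circRNA itself. At DT5 AT1G80640_C1 (chromosome 1, 30312632 to 30312873) dropped by 2.91 (SE 0.64, limma adjusted p = 1.45e-03), AT3G55330_C1 from the PsbP-like gene PPL1 (chromosome 3, 20514580 to 20514863) fell by 2.38 (SE 0.58, adjusted p = 3.27e-03), and AT1G45474_C4 from Lhca5 (chromosome 1, 17179610 to 17179940) fell by 1.98 (SE 0.53, adjusted p = 0.0109). AT1G23440_C1 (chromosome 1, 8323451 to 8324050) rose by 2.74 (SE 0.66, adjusted p = 3.27e-03), and the intergenic circRNAs AtciR19 (chromosome 1, 12381927 to 12382805) and AtciR83 (chromosome 1, 12381927 to 12382809), which share a start, by 1.02 (SE 0.28, adjusted p = 0.0126) and 1.64 (SE 0.49, adjusted p = 0.0296). These 3 rises and 3 falls were made among 236 circRNAs, with 41 at an unadjusted p under 0.05. The version fitted on the 4 libraries compared, which recovered fewer simulated changes, made no call at DT5. At DT4 AT3G55330_C1 alone was called, at -2.35 (adjusted p = 0.0130), among 259. At DT3 and DT2 0 of 235 and 0 of 248 were called by limma, with 21 and 10 at an unadjusted p under 0.05. Between DT5 and DT2 6 rose and 1 fell among 258, including AT1G57590_C1 (up by 2.35, SE 0.50, adjusted p = 8.22e-04), AT3G29390_C1 of RIK (up by 2.17) and AtciR28 (chromosome 2, 4485015 to 4486252, up by 0.94, SE 0.28). After rescaling limma called 2 rises and 3 falls at DT5, 1 and 1 at DT4, and 1 and 0 between DT5 and DT2, with 32 at an unadjusted p under 0.05 in the last.

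The most abundant Arabidopsis circRNA listed in every group, AT5G04090_C1 (exonic, chromosome 5, 1106879 to 1107381), had 1248 steps in WW and 1907 at DT5, a log2 change of 0.63 (SE 0.22) that did not pass the test (adjusted p = 0.0971). The smallest adjusted p of the planned test went to circRNAs at 0 in both libraries of a group. AtciR51 (plastid, 403 to 37035) had 2383 steps at DT2 and 0 in the other groups, AtciR108 (plastid, 403 to 77454) had 889 in WW alone, and AT4G07390_C1 (chromosome 4, 4196362 to 4197112) had 510, 0, 804, 974 and 759 steps from WW to DT5. The planned test called 268 higher and 284 lower at DT2, 260 and 304 at DT3, 343 and 285 at DT4, 384 and 312 at DT5, and 369 and 261 between DT5 and DT2, and 1267 circRNAs differed among groups. Of these calls 540, 544, 596, 652 and 593 had 1 of the groups at 0.

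**Figure D3:**
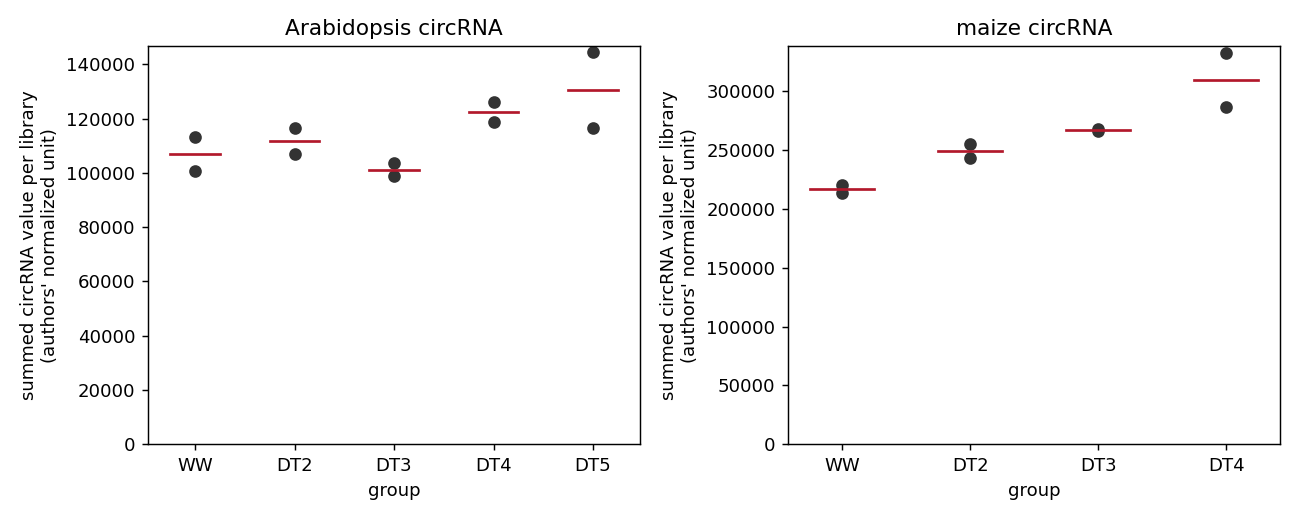
Summed circRNA value per library (vertical axis, the authors' scaled unit) in each group (horizontal axis) of Arabidopsis and maize, with points for libraries and lines for group means. In maize the mean is 217169 in WW and 309641 at DT4, and in Arabidopsis the 2 DT5 libraries lie at 116506 and 144528.

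The maize table held 2174 circRNAs, 1628 exonic, 457 intergenic and 89 intronic, from 1229 host genes, of which 306 had several, with a median length of 1033 bp (138 to 178864). Their number was 954 in WW, 1199 at DT2, 1223 at DT3 and 1451 at DT4, on 31145, 36149, 37775 and 46145 steps, and 447 were listed in every library. The summed value was 217169 ± 4933 in WW, 249048 ± 8221 at DT2, 266920 ± 832 at DT3 and 309641 ± 32265 at DT4 (SD, n = 2). The drought libraries listed 337 more on average than WW (planned two-sided exact permutation of libraries, p = 0.0714, the smallest this permutation can give), but both libraries of a group listed the same circRNAs. With groups permuted the exact permutation p was 0.5, the smallest possible with 4 groups.

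GRMZM2G088501_C1 (exonic, chromosome 6, 134057624 to 134058012, B73 RefGen_v3) rose from 117 steps in WW to 319, 628 and 775 at DT2, DT3 and DT4, a log2 change of 2.67 at DT4 (SE 0.24, limma adjusted p = 1.10e-19) and 1.42 at DT2 (adjusted p = 7.60e-06). The SE and p-values of this test rest almost wholly on a spread pooled over circRNAs, and hardly on that of each circRNA itself. GRMZM2G028914_C3 (chromosome 1, 77578201 to 77587154) rose by 2.44 at DT4 (SE 0.28, adjusted p = 5.31e-13). GRMZM2G121878_C9 (exonic, chromosome 3, 215553115 to 215553387) dropped by 0.52 (SE 0.17, adjusted p = 0.0187), and GRMZM2G055898_C1 (chromosome 3, 198457793 to 198458400) dropped by 1.31 (SE 0.34, adjusted p = 3.05e-03). Among maize circRNAs listed in both groups, 112 rose and 13 fell of 666 at DT4, 34 rose and 0 fell of 668 at DT3, and 3 rose and 0 fell of 697 at DT2 by limma, with 217, 131 and 64 at an unadjusted p under 0.05. After rescaling the counts were 24 and 36 at DT4, 5 and 3 at DT3 and 1 and 1 at DT2. Rescaling removes any shift shared by the circRNAs of a library. These counts thus do not tell whether the excess of rises lies in the scale of the values or in the circRNAs. The median change was 0.60 at DT4, 0.46 at DT3 and 0.28 at DT2, and 74.5% of the changes at DT4 were positive. Between DT4 and DT2 22 rose and 1 fell of 803, against 4 and 8 after rescaling. The planned test called 520 higher and 256 lower at DT2, 631 and 291 at DT3, 927 and 301 at DT4, and 747 and 411 between DT4 and DT2. Of these calls 732, 827, 1064 and 1041 had a group at 0, and 1801 maize circRNAs differed among groups.

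Some circRNAs listed in every library did not follow their hosts. AT3G47470_C1, from the light-harvesting gene LHCA4, had 15, 18, 11, 14 and 16 steps from WW to DT5 while the host fell by 3.22, so that its change exceeded that of the host by 3.36 at DT5 (limma adjusted p over all groups = 7.90e-04 among circRNAs listed in every library). AT5G43750_C1 and AT1G23480_C1 exceeded theirs by 3.23 and 3.01 (adjusted p = 2.34e-03 and 7.90e-04), and AT4G38550_C1 lay below its host, at -1.31 (adjusted p = 2.65e-03). Of 86 Arabidopsis circRNAs listed in every library with 1 tested host, 32 changed differently from the host, and of 369 in maize 42 did. A circRNA is in this set only if it had at least 2 steps in each library. One at few steps that fell with its host would have left the set. The set therefore cannot tell how often circRNAs fail to follow hosts that fall. Neither assay was rescaled for the counts of 32 and 42, so a shift shared by all values of a library enters every ratio. In maize at DT4 the median log2 change was 0.68 for such circRNAs and 0.21 for the hosts of the 369. How many of the 42 rest on such a shift was not tested. Over all circRNAs with 1 tested host the planned test called 1076 of 1177 and 1336 of 1691, most of them at 0 in some group. Such zeros have no spread and set the ratio against the host by themselves, so these counts do not tell how many circRNAs changed differently. The smallest adjusted p were those of AT4G07390_C1 (4.33e-10), AT5G24450_C1, AT4G10570_C1, AT5G66400_C1 of RAB18 and AT5G09870_C1 in Arabidopsis, which had a group at 0, as had GRMZM2G303631_C1 (2.20e-10) in maize.

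Across circRNAs, which are not independent replicates, the log2 changes of circRNA and host at the highest level against WW were correlated. Pearson's r was 0.290 (95% interval 0.237 to 0.341) and Spearman's rho 0.335 in Arabidopsis, with an r of 0.306 (0.263 to 0.349) and rho of 0.294 in maize. The intervals treat circRNAs as independent and hold no spread between libraries, so they understate the uncertainty. Among circRNAs listed in both groups r was 0.451 and rho 0.428 over 201 circRNAs of 170 hosts in Arabidopsis, and 0.413 and 0.376 over 542 circRNAs of 444 hosts in maize.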

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

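Results were recomputed under the alternatives fixed before the data were examined; the gene list tests with an estimated correlation, the fits of circRNAs listed in both groups or in every library, the permutation of groups, the transcript fits and the literal reading of the header were chosen after seeing the data. With 2 libraries in a group, leaving out 1 leaves a lone library assumed to vary like the other groups. The lower precision of such a fit can by itself end calls near the threshold. TPM keep no depth, and few steps a circRNA limit the circRNA calls. Where no cause is given, the cause was not tested.

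Without 1 library the calls ranged from 40 to 156 at Arabidopsis DT2, 712 to 1047 at DT3, 9792 to 11439 at DT4, 11941 to 13009 at DT5, 11598 to 12702 for DT5 against DT2 and 14446 to 15233 over all groups, and in maize from 38 to 112 at DT2, 1952 to 4994 at DT3, 8560 to 10901 at DT4, 6942 to 9895 for DT4 against DT2 and 9279 to 11565 over all groups. Each library left out at Arabidopsis DT2 (48 without WW replicate 1, 156 without WW replicate 2, 48 without DT2 replicate 1, 40 without DT2 replicate 2) and DT3 (1028, 854, 712 and 1047 in the same order) moved the count by over 1.5 times, as did each at maize DT2 (112, 71, 38 and 104), and at maize DT3 WW replicate 1 (2782), WW replicate 2 (2159) and DT3 replicate 1 (1952), and for maize DT4 against DT2 the omission of DT2 replicate 2 (6942). The planned circRNA calls ranged from 512 to 522, 515 to 523, 580 to 593 and 644 to 670 at Arabidopsis DT2 to DT5, 588 to 609 for DT5 against DT2 and 1229 to 1241 over all groups, and in maize from 590 to 634, 755 to 770 and 1080 to 1111 at DT2 to DT4, 1035 to 1065 for DT4 against DT2 and 1660 to 1724 over all groups. Ratio calls ranged from 1047 to 1108 in Arabidopsis and 1278 to 1345 in maize, host correlations from 0.285 to 0.293 and 0.290 to 0.313, and the excess of circRNAs listed under drought from 13.8 to 29.1 and 305 to 355.

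With TMM-like rescaling Arabidopsis DT3 had 2068 calls and with median centring 2022, and maize DT2 had 331 with median centring. The replicate block, which rests on numbers the libraries only share (correlations of same-number deviations from -0.160 to 0.0668 in Arabidopsis and -0.111 to 0.113 in maize), kept every count of linear and circRNA calls within 1.5 times, for example 272 at Arabidopsis DT2 and 13441 at DT5. For the ratio to the host this setting took the difference of circRNA and host between libraries of equal number. It kept the count of ratio calls of each species within 1.5 times too. Of the list tests 43 of 92 against WW passed at the preset correlation, 40 with the replicate block, where the kinase and dehydration lists at DT2 reached an adjusted p of 0.0524 and the plastid list at DT3 0.0616, and 0 with an estimated correlation, which is taken from the members of each list. The antioxidant list at DT3 went from an adjusted p of 0.0434 to 0.544 by camera at an estimated correlation of -0.0436. Correlated members alone thus do not account for every loss. The header of the Arabidopsis linear table read literally puts libraries of different groups under the same name, and limma then made 0 calls at DT2, DT3, DT4 and DT5, 0 for DT5 against DT2 and 0 over all groups, with 144, 1728, 7363, 7435 and 7304 genes at an unadjusted p under 0.05 in the first 5.

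Fewer genes were tested under the stricter filter on low values, with 7075 calls at Arabidopsis DT4, 7618 at DT5, 7468 for DT5 against DT2 and 8541 over all groups, and 7219 at maize DT4, 6365 for DT4 against DT2 and 7546 over all groups. No filter gave 205 at maize DT2. A log2 threshold of 1, which can only remove calls, left 178, 748, 4986 and 7556 at Arabidopsis DT2 to DT5, 7237 for DT5 against DT2 and 8711 over all groups, and 3229 and 7397 at maize DT3 and DT4, 6353 for DT4 against DT2 and 8132 over all groups. The fit of the groups compared alone gave 669 at Arabidopsis DT2. Transcripts in place of genes gave 62 and 1224 at Arabidopsis DT2 and DT3 and 270 at maize DT2.

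For circRNAs the stricter filter gave 288, 310, 316 and 376 at Arabidopsis DT2 to DT5, 329 for DT5 against DT2 and 589 over all groups, and 362, 482 and 585 at maize DT2 to DT4, 410 for DT4 against DT2 and 727 over all groups. Those listed in every library gave by limma 0, 0, 0 and 3 (7, 12 and 14 at an unadjusted p under 0.05 in the first 3), 3 for DT5 against DT2 and 0 over all groups in Arabidopsis, and 1, 24 and 82, 11 for DT4 against DT2 and 45 over all groups in maize. Those listed in both groups gave by limma 0, 0, 1 and 6 (10 and 21 at an unadjusted p under 0.05 in the first 2) and 7 for DT5 against DT2 in Arabidopsis, and 3, 34 and 125 and 23 for DT4 against DT2 in maize, and on the 4 libraries compared 0, 0, 7 and 0 (12, 20 and 34 at an unadjusted p under 0.05 where 0) and 2, and 1, 3, 88 and 32. That version was replaced after its counts had been seen, since it recovered 7.5% of 40 simulated changes in Arabidopsis and 0% in maize, against 27.5% and 12.5%. These recoveries come from 1 simulated table per species, scaled by each library's step for the version kept and left in steps for the other. A recovery of 0% does not describe the measured maize values, where that version made 88 calls at DT4. With TMM-like rescaling as well, limma gave 0, 0, 2 and 5 (13 and 20 at an unadjusted p under 0.05 in the first 2) and 1 for DT5 against DT2 in Arabidopsis, and 2, 8 and 60 and 12 for DT4 against DT2 in maize. The drop from the planned counts comes in part from the removal of circRNAs at 0 in a group. Of the planned calls 12, 20, 32 and 44 at Arabidopsis DT2 to DT5 and 44, 95 and 164 at maize DT2 to DT4 were listed in both groups, and the spread was estimated differently too. Ratio calls among circRNAs listed in every library were 32 in Arabidopsis and 42 in maize, and the host correlation was 0.217 with a pseudocount 10 times larger, 0.464 in every library and 0.451 in both groups in Arabidopsis and 0.419 and 0.413 in maize. Under a stricter detection minimum the Arabidopsis drought libraries listed fewer circRNAs than WW, -27.62, the reverse of the excess of 21.

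Of 209 tests of named genes, TMM-like rescaling left 196 on their side of the threshold, weakened 11 and reversed 2, median centring 193, 14 and 2, no filter 199 and weakened 10, pseudocounts 10 times smaller and larger weakened 4 and 7, the replicate block 6 and the groups compared alone 6, the log2 threshold 34, and the stricter filter left 167 and weakened 1. As for single omissions, leaving out 1 library left 714 and weakened 122. The reversals were at DT4 AT5G60390 (-0.10 rescaled, -0.065 centred) and PP2AA3 (-0.17 and -0.15). With the header read literally 193 weakened and at DT3 CYP707A3 was at -0.051, TCH4 at -0.037, PRR9 at 0.07, HSFA7A at -0.13, MYC2 at 1e-04, PAD4 at -0.17, WRKY70 at -0.91 and MYBR1 at -0.086. The alternatives not named here left each count of calls within 1.5 times and each other result on its side.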

Other observations

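Plastid circRNAs took between 19.8% and 43.4% of the steps of an Arabidopsis library, and the 2 libraries of DT2 held 43.4% and 30.1%. The plastid gene ATCG00020 alone had 118 of the circRNAs, and both plastid genes with several circRNAs had circRNAs on both strands. SAG12, a protease gene of late senescence, was listed at 0 in WW and at 105 ± 13.4 TPM (SD, n = 2) at DT4 (limma adjusted p = 2.91e-04), while its DT5 test had an adjusted p of 0.0638 (limma).

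The tests of counting noise, of depth, of host genes, of a common factor and of the share of abundant transcripts were chosen only after the result was seen, and the tests of the order of zeros among groups before. In Arabidopsis 78 circRNAs had 50 or more steps in a group and 0 in another, where counting of independent reads, 1 a step, gives an expected 7.05e-13. Counting error of such reads is argued against, as it is in maize with 98 against 7.37e-11, while reads copied from few molecules were not tested. Of 226 Arabidopsis circRNAs with 20 or more steps in a group and 0 in another, 36.7% had their zeros at an end of the order of drought levels, against 32.4% (SD 3.05) for shuffled groups. A loss or gain that follows the drought level is argued against for most of these, and a filter or calling step applied to each group apart may explain them and stays open, with no source to tell. In maize 55.4% of 327 had zeros at an end, against 46.4% (SD 2.73), a share above shuffled groups and below the bound set for a change with the level, so a separate filter and a change with drought cannot be told apart there because both could act on different circRNAs.

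The summed steps of maize circRNAs at DT4 were 1.48 times those of WW, while the relative depth, read from the inverse of the step, was 1.04 times. Deeper sequencing and a rise of circRNAs cannot be told apart by this, because no source gives the read depth or what a step stands for. After rescaling 40 of the 447 maize circRNAs listed in every library were called at DT4, 16 of them higher. Such changes in both directions go beyond a common factor, but whether a common factor for all circRNAs of a library made the excess of rises cannot be told apart from a wider rise of circRNAs, because rescaling removes a shift of either kind. The hosts of 369 such circRNAs changed by a median log2 of 0.21 against 0.68 for the circRNAs, which leaves open whether a rise of host RNA may account for part of the rise: the assays differ in scale, so that these medians do not decide it. A drought effect on circRNA formation or stability stays open as untested, and so does the unknown scaling by the authors.

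The median gene rose in TPM at each level, and the most abundant transcripts gave up share. The 50 genes most abundant in Arabidopsis WW held 28.7% of the TPM there and 2.77% at DT5, and those of maize WW 25.5% there and 4.97% at DT4. The shift expected from this loss was from 0.441 to 1.73 times the observed shift in each comparison with WW, and above it at Arabidopsis DT5 (1.73) and maize DT4 (1.3). The loss of share may thus account for a part of the excess of higher over lower calls, and whether it accounts for all of it cannot be told apart from a wider rise of other genes, because TPM keep no total RNA.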
